A study of Gasterosteus aculeatus with 62 samples.

How the data were processed

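Gene expression was measured by RNA sequencing in the diencephalon and the telencephalon of 31 male threespined sticklebacks, giving 62 libraries in 8 groups. Per the labels' protocols, both regions were dissected 1 hour after a behavioural trial, polyadenylated RNA was made into libraries with a stranded kit, and the libraries were sequenced together in a single lane. The deposited values were raw read counts per gene model, 1 file per library, in whole numbers, and no replicates were pooled. Per the submitters' processing notes, the authors used STAR and HTSeq. The versions, the genome build, the annotation and the strand setting of the counting are not given in the sources used here. Without the strand setting, reads of a gene and of an overlapping antisense gene cannot be assumed to be separated.

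The deposited counts listed 22295 gene models. Of these, 20805 had Ensembl stickleback identifiers, 657 were gene models named for the Y chromosome and 833 were other models named by the MAKER annotation pipeline. A total of 427 models had no count in any library. The counts in gene models averaged 35.6 M per library (SD 5.35, n = 62), with a range of 26.2 to 51.1 M. Per the tally lines of the deposited count files, 44.5% of the tallied reads were in gene models on average, 44.5% overlapped no gene model, 10.3% aligned to several places and 0.705% were ambiguous between models. The reads aligned to several places, 4.66% to 14.6% per library, were in no gene's count. Genes with near-identical copies, among them Y chromosome models with a close X copy, may therefore be undercounted, and their values are uncertain.

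None of the identifiers matched the table of gene names used here (assembly fGasAcu3.hap1.1, 52177 entries; 0 of 22295 matched). Genes are therefore given by identifier, with no symbol and no coordinates. The 26 gene lists fixed by symbol before the data were examined were not tested, for the same reason. The rule for naming genes, fixed at the same time, allowed at most 2 identifiers that rose and 2 that fell in a comparison whose genes have no symbol, by smallest p.

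The comparisons, tests, covariates and a set of alternatives were fixed before the data were examined. Each region was fitted alone, with the 31 libraries in 4 treatment groups, using edgeR 4.0.16 in R 4.3.3. Genes passed filterByExpr (minimum count 10, minimum total 15, smallest group 7), which left 18942 genes in the diencephalon and 18714 in the telencephalon. Library sizes were scaled by TMM, dispersions and quasi-likelihood fits were robust, and each contrast was tested with glmQLFTest. The p-values were adjusted by the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05. The 9 contrasts per region were the 6 pairs of treatments, the mean effect of the female, the mean effect of the predator cue, and the departure from additivity of both. A fit of all 62 libraries in 8 groups, with 19321 genes, gave the region comparison and the difference between regions of each treatment effect against control. A separate measure was the Pearson correlation across genes between effects estimated from libraries that do not overlap. The female effect without the predator cue was set against the female effect with it, and likewise for the predator cue. Genes are not independent replicates, so these correlations were judged against relabelled libraries.

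The alternatives fixed at that time were size factors by relative log expression, no expression filter, DESeq2 1.42.0, voom with sample quality weights (limma 3.58.1), 1 fit of all 62 libraries and, for the results on regions, a replicate block. The correlations were also computed over genes with a mean of at least 10 CPM and as Spearman correlations. Alternatives added after the data were seen left out the telencephalon library of predator male 42, used a regional index as a covariate, or combined these with the others. The regional index of a library was the mean log2-CPM (prior count 2) of the 500 genes highest in telencephalon over diencephalon minus that of the 500 genes lowest, among genes with a mean log2-CPM above 3. The library of male 42 was left out when the genes were chosen.

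The labels number the males, and the libraries of both regions with the same number come from the same animal. The deviations of log2-CPM from group means were checked for this pairing. Within males they correlated between regions at 0.198 to 0.550 (mean 0.380), against a mean of -0.0124 between different males. For 30 of the 31 males the telencephalon library correlated best with the diencephalon library of the same male. The region comparison did not include the male as a block, and its p-values treat the libraries of 1 male as independent.

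The fits were tested on simulated counts drawn from the real means, library sizes and dispersions, with known fold changes in 200 genes per draw. The simulated genes varied independently, which real genes do not. The Benjamini-Hochberg cutoff depends on how many genes change. The shares called therefore hold for 200 changed genes and would be lower for a response of few genes. For courtship against control in the diencephalon, edgeR called 34.2% of 199 genes changed 1.25-fold, 67.8% at 1.5-fold, 81.9% at 2-fold and 95.0% at 4-fold, with about 18839 genes tested per draw. For the same comparison in the telencephalon, with about 18624.5 genes tested, it called 18.2% of 198 genes, 48.7% of 199, 71.2% of 198 and 90.4% of 198 at those folds. For the predator cue in the telencephalon, the share of genes changed 1.5-fold that were called was 63.5% with dispersions from all libraries and 75.0% with male 42 left out, each of 200 genes. Every called changed gene had the right direction. Among unchanged genes, for courtship against control, DESeq2 called 82 of 74560 in the diencephalon and 81 of 73705 in the telencephalon over 4 draws. By edgeR these were 30 and 21, so DESeq2 made more false calls. It also called more of the changed genes, such as 70.9% at 1.5-fold in the diencephalon. Tests on the regional index were exact permutation tests for pairs of groups and permutation tests with 100000 draws for the 2 by 2 terms, all of them two-sided tests. Libraries were relabelled 100 times within a region and 40 times in the fit of 62 libraries, the actual labels included.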

Results

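Male threespined sticklebacks (Gasterosteus aculeatus) build a nest, court females and then guard the eggs alone, so a courting male in view of a predator faces competing demands. In this study nesting males met 1 of 4 treatments. These were empty cages (control, 7 males), a caged egg-bearing female (courtship, 8 males), a model trout with odour cues (predator, 8 males), or a female and a model trout together (tradeoff, 8 males). The labels name odour cues for the predator treatment and do not repeat them for the tradeoff, so the predator stimulus is not known to be identical in both. The diencephalon, which holds the hypothalamus and thalamus, and the telencephalon, the forebrain part that holds the pallium and subpallium, were sampled 1 hour after the trial. Each of the 62 libraries came from 1 region of 1 of the 31 males, so the spread within groups is the spread between animals. Counts in gene models averaged 35.1 M per diencephalon library (SD 5.21, n = 31, range 26.6 to 47.7 M) and 36.1 M per telencephalon library (SD 5.52, n = 31, range 26.2 to 51.1 M). The files pair no identifier with a gene name, and genes are given by identifier.

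The comparison of the regions asked which genes mark each of them, whatever the treatment. Of 19321 genes tested, 12861 differed between the telencephalon and the diencephalon at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). Of these, 6370 were higher in the telencephalon and 6491 in the diencephalon. Most differences were small, with a median absolute log2 fold change of 0.36 among the called genes. A difference of more than 2-fold was found for 865 genes higher in the telencephalon and 1303 higher in the diencephalon. More than 16-fold was reached by 32 and 86 genes. Among gene models named for the Y chromosome, 308 of 487 differed, 134 of them higher in the telencephalon and 174 in the diencephalon, and these counts are uncertain where reads are shared with a close X copy. Among models with Ensembl identifiers, 12349 of 18502 differed.

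The genes with the smallest p included large differences toward the telencephalon and smaller ones toward the diencephalon. ENSGACG00000008062 had 43.3 CPM in the telencephalon (SD 10.6, n = 31) and 3.25 in the diencephalon (SD 0.950, n = 31), a log2 fold change of 3.75 (SE 0.103, adjusted p = 5.85e-37). ENSGACG00000010350 had 91.7 CPM (SD 19.4) against 10.7 (SD 1.59), a log2 fold change of 3.10 (SE 0.0864, adjusted p = 9.39e-37). Higher in the diencephalon, ENSGACG00000008073 had 102 CPM there (SD 6.73, n = 31) and 41.2 in the telencephalon (SD 5.69, n = 31), a log2 fold change of -1.31 (SE 0.0392, adjusted p = 9.75e-36). The gene model maker-chrXII-exonerate_protein2genome-gene-35.23 had 57.9 CPM in the diencephalon (SD 5.66) and 27.4 in the telencephalon (SD 2.65), a log2 fold change of -1.08 (SE 0.0341, adjusted p = 1.60e-34).

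The plot of principal components showed the same separation. The first component of log2-CPM over 19321 genes held 42.6% of the variance and followed the regions, with 29 telencephalon libraries at 22.7 to 72.9. Between the regions lay the telencephalon library of control male 30 (-0.958). Predator male 42 had a telencephalon library that lay beyond the diencephalon libraries on the first component (-68.3) and apart from all others on the second (91.4). Its regional index, the mean log2 level of telencephalon-high genes minus that of diencephalon-high genes, was -1.95. The other 30 telencephalon libraries had 0.675 to 2.61 and the 31 diencephalon libraries had -1.21 to -0.854. Its depth was 36.5 M counts, within the range of the others.

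**Figure D1:**
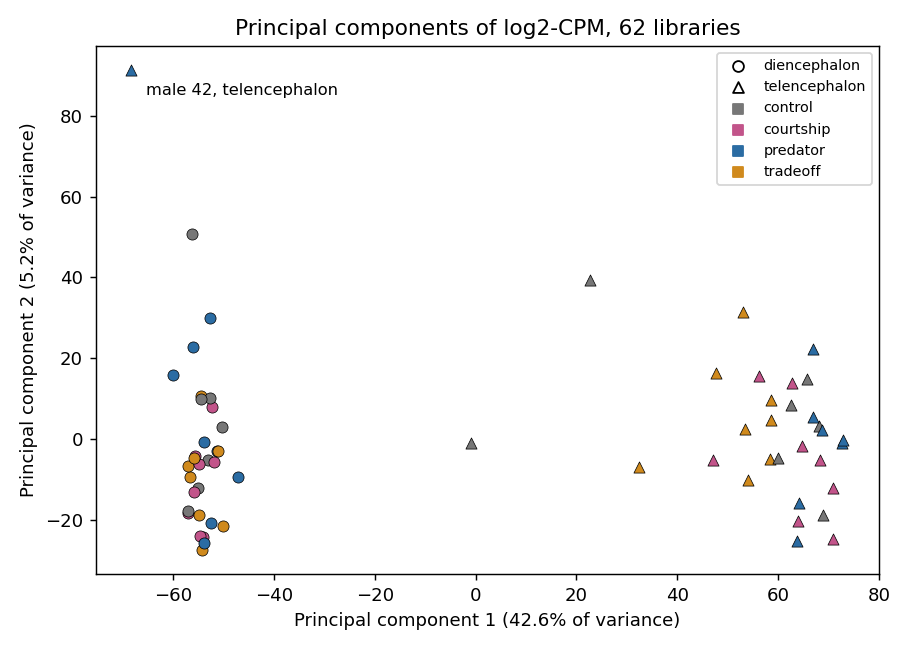
Principal components of log2-CPM in 62 libraries, where the horizontal axis is the first component (42.6% of variance) and the vertical axis is the second (5.2%), circles are diencephalon and triangles telencephalon libraries, and colours are treatments. The telencephalon library of male 42 lies at the upper left, at -68.3 and 91.4.

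The courtship comparison asked what a gravid female changes in the brain of a male that faces no predator. No gene passed the threshold between courtship and control in either region. In the diencephalon the smallest adjusted p was 0.778 and 860 of 18942 genes had an unadjusted p under 0.05 (edgeR quasi-likelihood test). The nominal rate of 0.05 gives 947.1 genes, and relabelled libraries gave a median of 793. In the telencephalon the smallest adjusted p was 0.569 and 555 of 18714 genes had an unadjusted p under 0.05. The nominal rate gives 935.7 there, and relabelled libraries gave a median of 918. Without the library of male 42, an alternative chosen after the data were seen, the actual telencephalon count was 1009 of 18687. Past the threshold were then 0 genes by edgeR and voom and 2 by DESeq2. The estimates were precise for most genes. The median standard error of the log2 fold change was 0.0961 in the diencephalon and 0.127 in the telencephalon. The 95% interval of the fold change lay within 2-fold in either direction for 88.5% and 84.4% of genes. DESeq2 called 7 and 3 genes, voom with sample quality weights called 0 and 0, and the fit of all 62 libraries called 0 and 12.

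The predator comparison asked the same of the model trout and its odour cues. With all libraries no gene passed the threshold between predator and control in either region, and 603 diencephalon and 671 telencephalon genes had an unadjusted p under 0.05 (edgeR quasi-likelihood test). The telencephalon result depended on the library of male 42. Without it, in an alternative chosen after the data were seen, 3 genes rose and 1 fell, and 1578 genes had an unadjusted p under 0.05. The smallest p among those that rose was that of ENSGACG00000010476, with a log2 fold change of 1.03 (SE 0.150, adjusted p = 0.00280 by edgeR). The gene that fell was ENSGACG00000014939, from 19.7 CPM in controls (SD 1.19, n = 7) to 15.7 in predator males (SD 1.097, n = 7), a log2 fold change of -0.33 (SE 0.0587, adjusted p = 0.0227 by edgeR). With the regional index as a covariate and male 42 left out, edgeR called 0 genes for predator against control, with 501 at an unadjusted p under 0.05. The log2 fold changes of the genes named here were then 0.90 (SE 0.161, adjusted p = 0.107) for ENSGACG00000010476 and -0.34 (SE 0.0656, adjusted p = 0.135) for ENSGACG00000014939. With all 31 libraries the log2 fold change of ENSGACG00000014939 was -0.31 (SE 0.0572, adjusted p = 0.127). DESeq2 with all libraries called 0 genes in the diencephalon and 1 in the telencephalon, voom with sample quality weights called 0 and 0, and the fit of all 62 libraries called 0 and 24.

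The tradeoff comparison asked what happens when both stimuli are present. No gene passed the threshold between tradeoff and control in either region, with 710 diencephalon and 420 telencephalon genes at an unadjusted p under 0.05 (edgeR quasi-likelihood test). DESeq2, voom with sample quality weights and the fit of all 62 libraries also called 0 genes in both regions. Without male 42, 663 telencephalon genes had an unadjusted p under 0.05, and 1 gene rose past the threshold by edgeR. It was the gene ENSGACG00000010476 described with the predator cue. At least 1 called gene was reached by 7 of 100 relabelings of these libraries, so chance is not excluded for this call. Against courtship alone, which differs by the model trout, no gene passed, with 634 and 846 genes at an unadjusted p under 0.05. DESeq2 called 0 and 1 there. Without male 42 the telencephalon count was 1580, with 0 past the threshold by edgeR. Against predator alone, which differs by the female and possibly by the odour cues, no gene passed, with 888 and 1001 genes at an unadjusted p under 0.05. DESeq2 called 3 and 2, and the fit of all 62 libraries called 0 and 54. Without male 42 the telencephalon count was 2261, with 0 past the threshold by edgeR, 2 by voom and 27 by DESeq2. With the regional index as a covariate as well it was 843. No gene passed between courtship and predator males either, with 1238 and 929 genes at an unadjusted p under 0.05. DESeq2 called 1 and 2 genes, and the fit of all 62 libraries called 0 and 61. Voom with sample quality weights called 0 genes in these 3 comparisons in both regions.

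The 4 treatments form a 2 by 2 layout, in which the mean effect of each stimulus uses all 31 males. The mean effects and the departure from additivity take the predator cue as the same in both treatments that have it. The mean effect of the predator cue was tested in the telencephalon and then in the diencephalon. With all libraries no gene passed, the smallest adjusted p was 0.998 and 609 genes had an unadjusted p under 0.05 (edgeR quasi-likelihood test). Voom with sample quality weights called 1 gene, DESeq2 called 0 and the fit of all 62 libraries called 3. Without the library of male 42, an alternative chosen after the data were seen, 7 genes passed and all 7 were higher with the predator cue. Their median log2 fold change was 0.69, with a range of 0.47 to 0.89. With male 42 included it was 0.60, and each of the 7 had an unadjusted p under 0.05.

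ENSGACG00000010476 had the smallest p of these genes. Its level in the telencephalon was 36.3 CPM in controls (SD 6.55, n = 7), 43.5 in courtship males (SD 9.41, n = 8), 74.3 in predator males (SD 8.69, n = 7 without male 42) and 73.6 in tradeoff males (SD 17.8, n = 8). The predator cue effect was a log2 fold change of 0.89 (SE 0.102, adjusted p = 2.43e-05 by edgeR), and all 15 libraries with the cue lay above the highest control. Courtship males, which also lacked the cue, reached 57.6 CPM, and 14 of the 15 lay above the highest library without the cue. Over the 7 genes, 5 to 14 of the 15 did. The library of male 42 held 4.44 CPM. With it, the log2 fold change of ENSGACG00000010476 was 0.81 (SE 0.207, adjusted p = 0.998). ENSGACG00000017076 rose from 14.4 CPM in controls (SD 4.04, n = 7) and 17.1 in courtship males (SD 3.43, n = 8) to 26.6 in predator males (SD 5.75, n = 7) and 26.0 in tradeoff males (SD 4.95, n = 8). Its log2 fold change was 0.75 (SE 0.117, adjusted p = 0.00489 by edgeR), and 0.65 (SE 0.228, adjusted p = 0.998) with male 42 included.

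**Figure D2:**
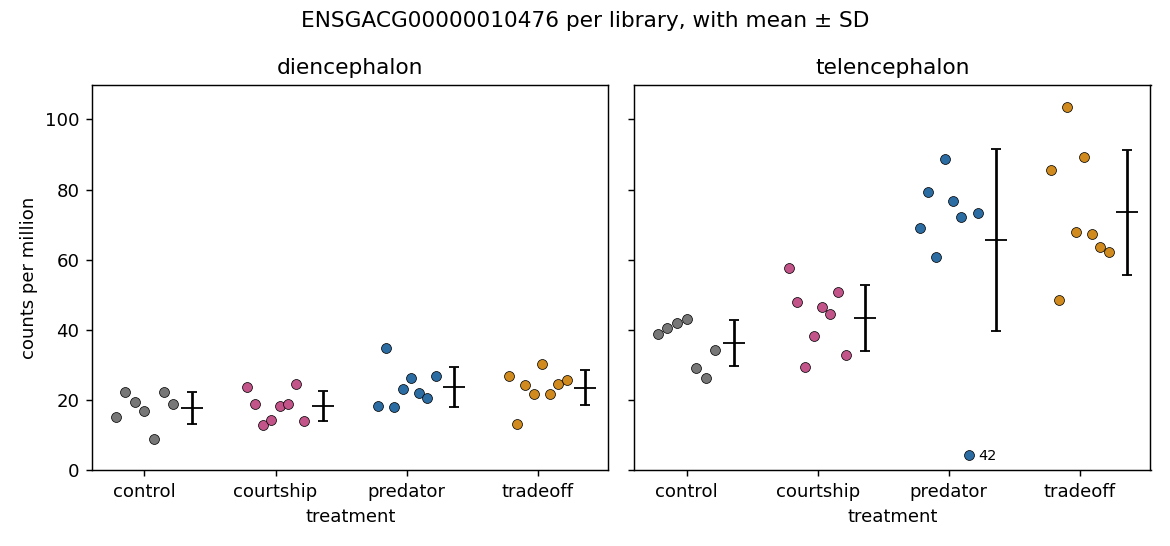
Level of ENSGACG00000010476 in each library, where the vertical axis is CPM (counts scaled to library size), each dot is a library of the treatment on the horizontal axis, and the bar beside each group is the mean ± SD of all its libraries. In the telencephalon, predator and tradeoff libraries had 48.5 to 104 CPM except male 42 at 4.44. Control libraries had 26.4 to 43.1 CPM and courtship libraries 29.6 to 57.6 CPM.

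In the diencephalon the same 7 genes were all estimated higher with the predator cue, with a median log2 fold change of 0.21. No gene passed there, and 4 of the 7 had an unadjusted p under 0.05. Both regions came from the same males, and relabelled treatments gave a median correlation of 0.370 between the predator cue effects of the regions. Genes chosen for a high telencephalon effect may thus lean the same way in the diencephalon without a response, so this is not independent evidence. ENSGACG00000010476 had 17.7 CPM in control (SD 4.67, n = 7), 18.3 in courtship (SD 4.32, n = 8), 23.7 in predator (SD 5.60, n = 8) and 23.5 in tradeoff diencephalon (SD 5.03, n = 8), a log2 fold change of 0.39 (SE 0.125, adjusted p = 1.00 by edgeR). The difference between the regions in the predator cue effect, tested without male 42, was 0.50 on the log2 scale (SE 0.165, edgeR adjusted p = 1.00 over all genes and 0.00663 over these 7 genes alone). These 7 genes had been chosen for their telencephalon effect, so the latter value is not independent evidence. Over all diencephalon genes the predator cue gave 625 at an unadjusted p under 0.05 and 0 past the threshold by edgeR, by DESeq2 and by voom.

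The mean effect of the female gave no called gene in either region, with 1213 diencephalon and 621 telencephalon genes at an unadjusted p under 0.05 (edgeR quasi-likelihood test). DESeq2 called 1 and 0 genes, and voom called 0 and 0. The departure from additivity, which asks whether the response to both stimuli differs from the sum of the single responses, gave no called gene either. There were 572 diencephalon and 911 telencephalon genes at an unadjusted p under 0.05. DESeq2 called 1 and 0 genes, voom called 0 and 0, and the fit of all 62 libraries called 0 and 10. Without male 42 the telencephalon count of genes at an unadjusted p under 0.05 rose to 2862 of 18687, still with 0 past the threshold by edgeR. DESeq2 then called 115 and the fit of 61 libraries called 203. With the regional index as a covariate as well the count at an unadjusted p under 0.05 was 639, and relabelled libraries gave a median of 838. The telencephalon regional index departed from additivity in the same libraries (-0.79, permutation p = 0.00302), but not with male 42 included (-0.24, permutation p = 0.826). Its mean was 1.95 in controls (SD 0.683, n = 7), 2.29 in courtship males (SD 0.251, n = 8), 2.43 in predator males (SD 0.140, n = 7 without male 42) and 1.99 in tradeoff males (SD 0.264, n = 8). Control males 30 and 12 had 0.675 and 1.32, against 2.14 to 2.45 in the other controls. Without these and male 42 the control mean was 2.33 (SD 0.122, n = 5) and the departure was -0.40 (permutation p = 0.0445).

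**Figure D3:**
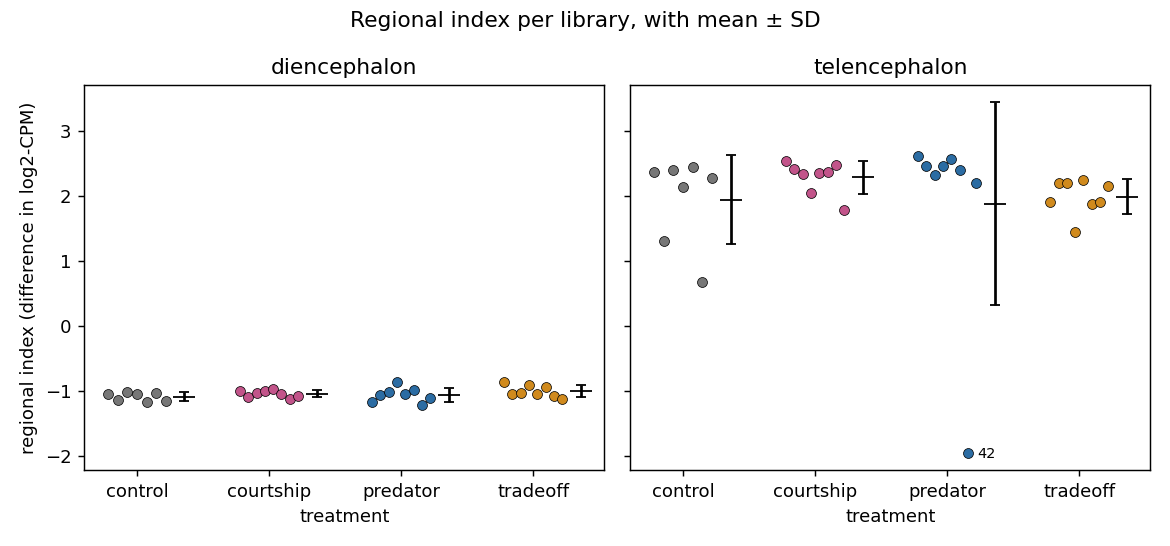
Regional index of each library, where the vertical axis is the mean log2-CPM of telencephalon-high genes minus that of diencephalon-high genes, each dot is a library of the treatment on the horizontal axis, and the bar beside each group is the mean ± SD of all its libraries. The telencephalon library of predator male 42 lies at -1.95, below every diencephalon library.

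The effects of 1 stimulus with and without the other were then compared across genes. In the diencephalon the female effect without the predator cue and the female effect with it correlated at 0.158, and 12 of 100 relabelings gave a correlation at least as far from 0. Over the 11620 genes with a mean of at least 10 CPM the correlation was 0.328, reached by 4 of 100 relabelings. The 2 estimates of the predator cue effect correlated at -0.00334 in the diencephalon, reached by 96 of 100. In the telencephalon the correlations were -0.0830 for the female and -0.119 for the predator cue, reached by 56 and 44 of 100. Without male 42 they were -0.336 and -0.305, reached by 1 and 2 of 100. Over genes with a mean of at least 10 CPM they were -0.635 and -0.552, reached by 2 and 6 of 100, so that of the predator cue did not pass there. In these libraries, genes with a higher estimated effect of 1 stimulus alone thus tended to have a lower one when the other stimulus was present. Both correlations and the departure from additivity are computed from the same group means, so they are not separate results. With the regional index as a covariate as well, the correlations were -0.0767 and -0.0612, reached by 44 and 51 of 100, and over genes of at least 10 CPM they were 0.209 and 0.179, reached by 37 and 44 of 100.

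The difference between regions of each treatment effect was tested in the fit of all 62 libraries. No gene passed for courtship, predator or tradeoff against control, with 394, 366 and 239 of 19321 genes at an unadjusted p under 0.05 (edgeR quasi-likelihood test). DESeq2 called 6, 2 and 2 genes, and voom called 0, 0 and 0. With the male as a replicate block, the counts past the threshold were also 0 in all 3, with 449 to 640 genes at an unadjusted p under 0.05. Without male 42, 1 gene passed for predator against control, with a lower effect in the telencephalon. With the male as a block as well, 0 passed, and 866 to 1486 genes had an unadjusted p under 0.05 by edgeR.

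**Figure D4:**
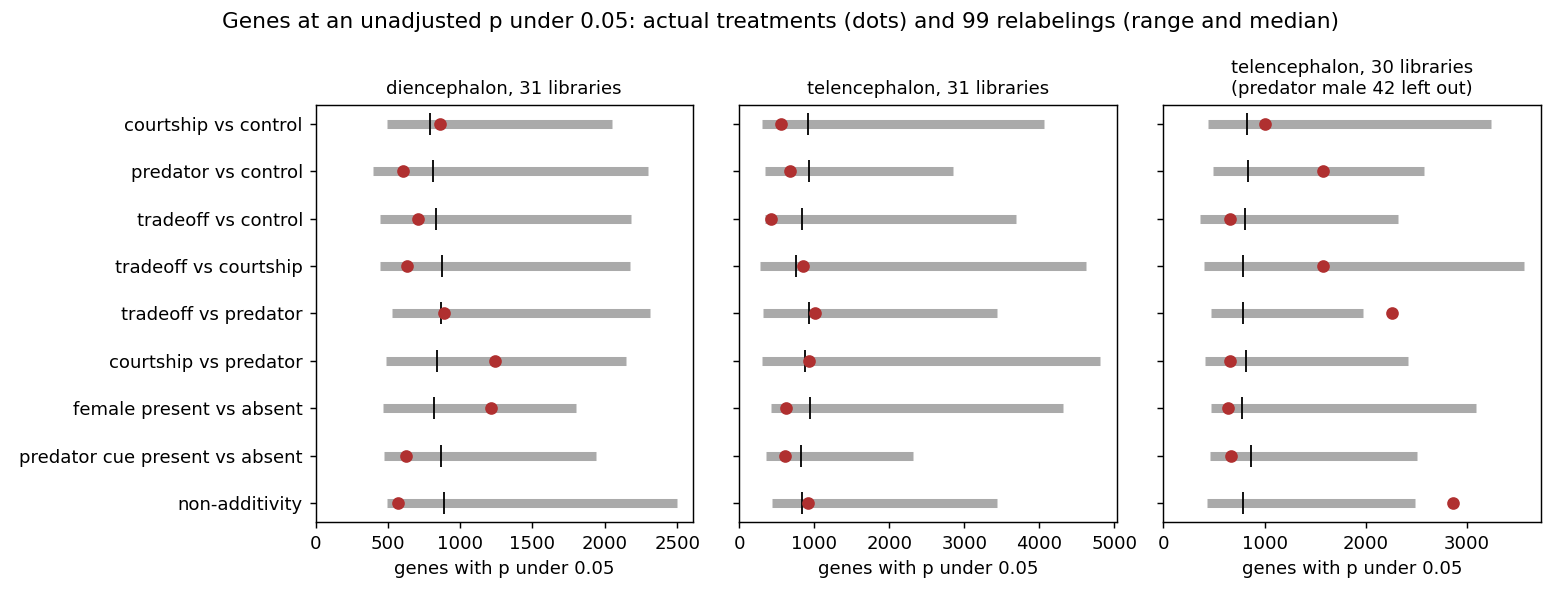
Number of genes at an unadjusted p under 0.05 in each comparison, where the horizontal axis is the number of genes, dots are the actual treatments, grey bars span 99 relabelings and black ticks are their medians, in the diencephalon, the telencephalon and the telencephalon without male 42. Only in the last panel do dots lie beyond the bars, for tradeoff against predator (2261 genes) and for non-additivity (2862 genes).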

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

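Of the tests in this part, those of the male 42 library were chosen after its values were seen, apart from the test of whether the male differs in both regions, and every value without that library is an alternative chosen after the data were seen. A single library stood far from the others of its group in 13 of 96 groups tested. About 4.8 would be expected for independent measures that were not chosen from the data. The measures included levels of genes chosen from these same data. Among them, ENSGACG00000010476 and ENSGACG00000017076 were chosen from the fit without male 42. The number of flagged groups is therefore not a test against chance.

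The telencephalon library of predator male 42 accounted for 6 of the 13 flagged groups. Its regional index was -1.95, against 2.202 to 2.61 in the other predator males, and 11.8% of its counts were in the 10 most counted genes, against 8.09% to 9.83%. ENSGACG00000010350 had 20.4 CPM in it, against 78.1 to 114, and ENSGACG00000008073 had 51.4, against 38.9 to 44.4. ENSGACG00000010476 had 4.44 CPM, against 60.8 to 88.6, and ENSGACG00000017076 had 0.967, against 20.4 to 35.0.

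A swap with the diencephalon library of the same male is argued against by the regional index of that library, -1.21, which is a diencephalon value. Diencephalon tissue like that of the others is argued against by the index of -1.95, below all 31 diencephalon libraries (mean -1.04, SD 0.0848), and low depth by its 36.5 M counts. A total of 34 genes were more than 4-fold above the highest of the other 61 libraries in it, and no other library had more than 3 such genes, which is consistent with RNA of a tissue that the other libraries lack. A male that differs in both regions cannot be told apart from this, since 5 of those genes were highest in the diencephalon library of male 42 among 31, more than the 1.097 that chance gives but far from most of them. Which tissue it may be was not tested, because the genes have no names here, and no biological explanation was tested.

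The other outlying values were single libraries. The telencephalon library of courtship male 38 had 51.1 M counts, against 33.3 to 38.0 M. The diencephalon library of control male 15 had 47.3% of its tallied reads in genes, against 43.03% to 44.65%. The telencephalon library of tradeoff male 13 had a regional index of 1.45, against 1.88 to 2.24, and 31.5 CPM of maker-chrXII-exonerate_protein2genome-gene-35.23, against 22.3 to 26.4. ENSGACG00000008062 had 22.8 CPM in the telencephalon of control male 26, against 41.9 to 56.0. ENSGACG00000010350 had 16.2 CPM in the diencephalon of control male 12, against 7.99 to 10.9. ENSGACG00000017076 had 6.29 CPM in the diencephalon of control male 26, against 8.66 to 10.02.

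The predator cue effect differed between regions for 5 of the 7 telencephalon genes when adjusted over these genes alone, with male 42 left out. The difference was 0.50 on the log2 scale for ENSGACG00000010476 (SE 0.165, edgeR adjusted p = 0.00663 over the 7) and 0.53 for ENSGACG00000017076 (SE 0.155, edgeR adjusted p = 0.00441 over the 7). With the male as a block and both libraries of male 42 left out, these differences were 0.48 (SE 0.107, edgeR adjusted p = 0.000254 over the 7) and 0.56 (SE 0.113, edgeR adjusted p = 8.07e-05 over the 7), and 5 of the 7 again passed. Over all genes no difference passed by edgeR (adjusted p = 1.00 for both unblocked, 0.701 and 0.222 blocked), and the genes had been chosen for their telencephalon effect.

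For the 7 genes themselves, regional composition as measured by the index is argued against as the whole cause. All 7 passed with the index as a covariate. The index itself differed little with the cue in these libraries (0.094, permutation p = 0.570), so the covariate could change little. A difference in composition that the index does not measure was not tested. It matters here because all 7 genes had a higher control mean in the telencephalon than in the diencephalon. Examples are ENSGACG00000010788 (10.3 against 2.16 CPM) and ENSGACG00000010476 (36.3 against 17.7 CPM). All 7 were also lower in the library of male 42 than in any other predator telencephalon library. For ENSGACG00000010788 the level was 1.09 CPM, against 12.8 to 31.7. Chance is argued against only for the 30 libraries without male 42. Of 100 labelings, 1, the actual one, called as many as 7, and the highest of the others called 2. With the index as a covariate, 2 of 100 reached the 8 genes called, and the highest of the others called 50. The 668 genes at an unadjusted p under 0.05 by edgeR without the covariate were reached by 77 of 100. The relabelings do not allow for the choice of leaving out male 42, made after the data were seen. Dependence on a single other library is argued against because at least 6 of the 7 were called whichever of the remaining 30 libraries was left out, and ENSGACG00000016157 was the gene lost, kept in 21 of 30 fits. A telencephalon response to the predator cue is therefore a hypothesis that these tests leave open, found and tested on the same data. A difference in composition outside the index is left open as well. With male 42 included all 7 genes were still estimated higher, each at an unadjusted p under 0.05, with a median log2 fold change of 0.60 against 0.69 without that library. Of the 7, edgeR then called 0, voom with sample quality weights 1, DESeq2 0, and edgeR with the regional index as a covariate 3.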

How the results depend on the processing

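Values without male 42, with the regional index as a covariate and from the fit of 61 libraries are alternatives chosen after the data were seen, and the others were fixed before. Of the counts of called genes, 90 of 110 values fixed before and 52 of 80 added ones were kept. Every comparison but that of the regions called 0 genes in the main fit, so a kept count there was 0 again. Only for the region comparison was a count within 1.5 times taken as kept. Of the correlations, 9 of 12 fixed before and 5 of 8 added ones kept direction and side of the threshold. Of the single genes, 32 of 35 fixed before and 13 of 28 added values kept both, and the other 3 and 15 newly passed the threshold. The region comparison called 12861 genes and 12872 to 14928 under its alternatives. Size factors by relative log expression and no expression filter called 0 genes in all treatment comparisons, with 242 to 1246 and 417 to 1462 at an unadjusted p under 0.05 by edgeR. With the replicate block, which pairs the regions of a male, 14359 genes differed between regions (14928 without male 42), the differences between regions of treatment effects called 0, 0 and 0. Without male 42 the block took the call for predator against control from 1 to 0, and it moved no other count of calls by over 1.5 times.

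By DESeq2 the diencephalon counts were 7 for courtship against control, 3 for tradeoff against predator, 1 for courtship against predator, 1 for the female and 1 for non-additivity. The telencephalon counts were 3 for courtship and 1 for predator against control, 1 for tradeoff against courtship, 2 for tradeoff against predator and 2 for courtship against predator. The differences between regions gave 6, 2 and 2. Voom with sample quality weights called 1 gene, for the predator cue in the telencephalon. The fit of all 62 libraries called 12 telencephalon genes for courtship and 24 for predator against control, 54 for tradeoff against predator, 61 for courtship against predator, 3 for the predator cue and 10 for non-additivity. It pools the spread of both regions, and its comparisons of treatments within a region were not run on relabelled libraries.

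Without male 42, edgeR called 4 telencephalon genes for predator and 1 for tradeoff against control, 7 for the predator cue, and 1 for the difference between regions of predator against control. DESeq2 without male 42 called 2, 13 and 7 for courtship, predator and tradeoff against control, 2 for tradeoff against courtship, 27 for tradeoff against predator, 2 for courtship against predator, 1 for the female, 15 for the predator cue and 115 for non-additivity. Voom without male 42 called 2 for predator against control, 1 for tradeoff against control, 2 for tradeoff against predator and 7 for the predator cue. The regional index as a covariate gave 2 for tradeoff against courtship and 3 for the predator cue with all libraries. Without male 42 it gave 4 for tradeoff against control, 2 for tradeoff against courtship, 8 for the predator cue and 0 for predator against control (501 at an unadjusted p under 0.05 by edgeR). The fit of 61 libraries called 24, 34 and 5 for courtship, predator and tradeoff against control, 12 for tradeoff against predator, 13 for the predator cue and 203 for non-additivity.

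The diencephalon correlation of the female effects passed at a mean of 10 CPM or more (0.328) and was 0.0719 with the regional index. That of the predator cue effects, -0.00334, changed sign at 10 CPM or more (0.0929), as a Spearman correlation (0.0312) and with the regional index (0.0346), all near 0. The telencephalon correlations passed without male 42 (-0.336 and -0.305), but at 10 CPM or more that of the predator cue did not (-0.552, reached by 6 of 100 relabelings). With the regional index as well they were -0.0767 and -0.0612, and neither passed. The cause of the diencephalon changes was not tested. Tests of the 26 gene lists were not run, because no identifier matched a symbol. In simulated counts for the difference between regions of courtship against control, edgeR called 40.0% of 100 genes changed 1.5-fold and 70.7% of 99 changed 2-fold, so smaller effects would often be missed.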

Other observations

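The tests on the regional index, on genes that vary by male and on the genes called by DESeq2 were chosen after the data were seen, and relabelled libraries and the comparison of effects between regions were set out before their results were seen. Many genes differed between individual males in the same way in both regions. Across 30 males, with male 42 left out, the deviations from group means correlated between regions with a median of 0.384 over 19321 genes, against at most 0.0937 in 100 shuffles of the males. A correlation over 0.9 was found for 372 genes, against at most 3 in the shuffles. The median SD of these genes between males was 0.647 on the log2 scale, against 0.179 over all genes, and for 128 of them at least 1 male lay more than 4-fold below the median. Among gene models named for the Y chromosome, 15 of 487 were in this set (3.08%), and among Ensembl models 352 of 18502 (1.90%). Inherited or lasting differences between males are a candidate explanation. The libraries were not genotyped, and a gene missing or diverged in some males was not tested for. The shuffles could have come out the other way, but they break any likeness between the 2 libraries of a male, whatever its source. They cannot tell lasting differences from conditions that the 2 samples shared in sampling or library preparation, which were not tested.

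The 16 genes that DESeq2 called in any treatment comparison with all libraries had a median correlation between regions of 0.711. Of 10000 random sets matched by class of spread in the diencephalon, 4.19% were as high, with a median of 0.4925. Spread in the telencephalon was not matched. Part of those calls may therefore be genes that differ between males whatever the treatment.

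The effects of treatment in both regions of the same males correlated at 0.288 to 0.446 across 19321 genes in the 9 comparisons. Relabelled treatments gave medians of 0.370 to 0.404, and 0 of the 9 comparisons lay beyond 95 of 100 relabelings. A response common to both regions thus cannot be told apart from differences between males, which any grouping of the same males carries into both regions.

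Without male 42, non-additivity in the telencephalon gave 2862 genes at an unadjusted p under 0.05. For these 30 libraries 1 of 100 labelings, the actual one, gave as many, and the highest of the others gave 2490. The relabelings do not allow for the choice of leaving out male 42, made after the data were seen, nor for the choice among 9 contrasts. With all libraries the count was 911, reached by 42 of 100, so chance is not excluded. The count rests in part on single libraries, and relabelings were not run with a further library left out. It was 2010 without control male 30, 2176 without control male 12 and 2445 without courtship male 7, and 2492 to 3603 without any other library. The regional index of control males 30 and 12 was 0.675 and 1.32, against 2.14 to 2.45 in the other controls. With the regional index as a covariate the count was 639, below the 838 that relabelled libraries gave as a median. The absolute correlation of the index with the first principal component of these 30 libraries was 0.924. The covariate thus removes most of their main axis of variation, whatever its source, and the fall is not specific to regional composition. The regional index itself was not additive in these libraries (-0.79, permutation p = 0.00302, adjusted p = 0.0136 over 9 comparisons) and was lower in tradeoff than in predator males (-0.44, exact permutation p = 0.000777, adjusted p = 0.00699, two-sided). The departure of the index was -0.87 to -0.57 when any 1 further library was left out (highest permutation p = 0.00994) and -0.40 without control males 30 and 12 (permutation p = 0.0445, unadjusted), so much of its size rests on those controls. In the same libraries, 1 of 100 labelings gave as many as the 2261 genes of tradeoff against predator (highest other 1977), 11 as many as the 1580 of tradeoff against courtship (3568) and 32 as many as the 1009 of courtship against control (3236). For predator against control 13 gave as many as 1578 (2581), and for tradeoff against control 80 as many as 663 (2316). With the index as a covariate tradeoff against predator gave 843 genes, reached by 46 of 100. With male 42 included the non-additivity of the index had a permutation p of 0.826. Tradeoff minus predator males was then 0.11 in the index (exact permutation p = 0.9998), with the sign reversed. The library of male 42 stood apart on this same index, so the tests without it are not independent of the choice to leave it out. A different regional composition of the dissected tissue is a candidate explanation of the 2862 genes, and whether it came from dissection or from a change of expression within the tissue was not tested.

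Chance could not be excluded for any treatment comparison with all libraries, by the number of genes at an unadjusted p under 0.05. In the diencephalon, 39 of 100 labelings gave as many as the 860 of courtship against control (highest other 2047), 89 as many as the 603 of predator (2296) and 70 as many as the 710 of tradeoff (2182). For tradeoff against courtship 90 gave as many as 634 (2172), for tradeoff against predator 48 as many as 888 (2310), and for courtship against predator 18 as many as 1238 (2148). For the female 12 gave as many as 1213 (1798), for the predator cue 86 as many as 625 (1941) and for non-additivity 94 as many as 572 (2502).

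In the telencephalon, 69 of 100 gave as many as the 555 of courtship against control (highest other 4063), 67 as many as the 671 of predator (2850) and 87 as many as the 420 of tradeoff (3690). For tradeoff against courtship 47 gave as many as 846 (4625), for tradeoff against predator 45 as many as 1001 (3430), and for courtship against predator 48 as many as 929 (4803). For the female 84 gave as many as 621 (4311), for the predator cue 77 as many as 609 (2308) and for non-additivity 42 as many as 911 (3437). Several relabelings gave several times the actual count, and whether this comes from a structure of the samples or from correlation between genes was not tested. For the differences between regions of the effects against control, 23 of 40 gave as many as 394 for courtship (1615), 20 as many as 366 for predator (2205) and 32 as many as 239 for tradeoff (1523). For the region comparison chance is argued against, because 1 of 40, the actual one, called 12861 genes and the highest other called 7563.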
